A study of Mus musculus with 10 samples.

How the data were processed

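Sorted bone marrow progenitors of adult C57BL/6 mice were profiled on Affymetrix arrays from total RNA extracted with Trizol and labelled with biotin. Lineage-negative cells with high cKit, Sca-1 and Flt3, the lymphoid-primed multipotent progenitors (LMPPs), came as CD127− and CD127+ groups of 3 arrays each. Cells with low cKit and Sca-1, high Flt3 and CD127, the common lymphoid progenitors (CLPs), came as Ly6D− and Ly6D+ groups of 2 arrays each. The replicate number of each array was read from its title. The sources used here do not say whether replicates were separate animals or separate sorts, so p-values measure only the spread between these samples.

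The deposited table holds a value for each of 269751 probe sets on each of 10 arrays. The authors' values were read as log2 signals from their range of 0.20433 to 14.7901, which held no negative value, since the log base is not given in the sources used here. The submitters' processing notes name Affymetrix Power Tools. The summary method, the normalization and the genome build are not given in the sources used here. The quartiles of the arrays differed by 0.1252, 0.0493 and 0.1024 log2 at most, below a limit of 0.5 set for further normalization, so none was applied. The number of arrays limits the precision.

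Probe sets with 1 gene symbol (233753) were averaged into 23152 genes, with a median of 8 probe sets per gene and 2319 genes resting on 1 probe set. Another 5106 probe sets carried several symbols and 30892 carried none, and these stayed out of the gene tests. Against the GRCm38.p6 gene table, used for names alone, 20875 of the symbols were current, 2274 were older synonyms and 3 were absent.

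Differences were estimated with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups and default empirical Bayes settings, and p-values were adjusted by the Benjamini-Hochberg method over all 23152 genes at a threshold of 0.05. CD127+ LMPPs were compared with CD127− LMPPs, CLPs (the equal mean of their 2 groups) with each LMPP group, and Ly6D+ CLPs with Ly6D− CLPs. Each CLP group was also compared with each LMPP group. Errors of differences are standard errors (SE) from limma, and errors of group means are standard deviations (SD). Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

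Gene lists of sort markers, progenitor and blood lineages, other marrow cell types and cell processes were fixed before the data were examined. Those with at least 5 measured members, 22 in all, were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of each comparison. Camera with an estimated correlation and fry were the alternatives. The lists share members. The early lymphoid list shares Rag1, Rag2, Dntt and Foxo1 with the B lineage list, Ccr7 and Ccr9 with the homing list, Il7r with the sort markers, Notch1 with the T lineage list and Tcf4 with the dendritic cell list. The dendritic cell list also shares Spib with the B lineage, Ly6c2 with the macrophage and Irf7 with the interferon list. The innate lymphoid list shares Gata3 and Tcf7 with the T lineage and Itga4 and Itgb7 with the homing list. Ccr2 and Vcam1 are on the homing and macrophage lists, and Lef1 on the B and T lineage lists. The ribosomal protein list takes each symbol that begins with Rpl or Rps and a digit, so it also holds the kinase genes Rps6ka1 and Rps6ka6, and Rps19bp1, Rpl3l and Rps15a-ps6. A second neutrophil list, a second erythroid list, an eosinophil and basophil list and a set of sensory receptor genes were written later, before their values were read.

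Genes were named by a rule written at the same time as these lists. It takes the 8 largest differences in each direction past the threshold with no overlap between the arrays of the sides compared, leaving out predicted, small RNA, immunoglobulin and T cell receptor genes. It adds the 5 sort markers and, from each list, up to 4 members past the threshold or else the largest difference. Further list members, named because a count was 5 or fewer, were chosen after their values were seen.

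The steps were tested on simulated data with 500 changed genes per size over 5 simulations. For a log2 change of 1, 70.2% of the changed genes were recovered between the LMPP groups, 73.6% between CLPs and CD127+ LMPPs and 38.8% between the CLP groups. For a log2 change of 2 the shares were 96.4%, 98.8% and 95.4%, and 3.7%, 5.1% and 4.8% of the calls were false. The simulated errors were independent and normal, with variances drawn from the limma fit itself. These shares therefore check the steps and do not measure the false calls among the real arrays.

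The alternatives were quantile normalization, median centring, the median or the brightest probe set of a gene, a filter on dim genes, limma with trend and robust settings, a fit of the compared arrays alone, a replicate block, array weights, a 2-fold threshold, either CLP group alone, the 2 other list tests, and each array left out in turn. For the correlation between comparisons, members of the fixed lists were left out as well. Leaving out the 2 arrays of largest residual spread, leaving out small RNA and sensory receptor genes, and separate CD127− LMPP arrays for the covariance of the 2 comparisons that share them, were added after seeing the data. The LMPP and the CLP arrays were registered as separate blocks and the labels name no array batch, so a batch cannot be told apart from the difference between LMPPs and CLPs. No group held 4 arrays, so single arrays were not tested for standing apart from their group.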

Results

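Gene expression was measured in 4 sorted progenitor groups of adult mouse bone marrow: CD127− LMPPs (n = 3 arrays), CD127+ LMPPs (n = 3), Ly6D− CLPs (n = 2) and Ly6D+ CLPs (n = 2). CD127 is the α chain of the interleukin 7 receptor, encoded by Il7r. The study divided LMPPs by CD127 and compared both parts with CLPs. Gene values are on a scale read as log2. Differences called largest are so among the genes that the naming rule admits, which leaves out predicted, small RNA, immunoglobulin and T cell receptor genes. Within groups, pairs of arrays correlated at Pearson r of 0.9725 to 0.9855 across genes. The lowest was that of the 2 Ly6D− CLP arrays. Ly6D− CLP array 1 correlated more closely with the Ly6D+ CLP arrays (0.9792 and 0.9772), and an LMPP pair from different groups reached 0.9811. Sensory receptor genes, a reference for low signal, had a median value of 2.55 and a 95th percentile of 4.54, against a median of 4.59 for all genes. Where a group mean on the dimmer side lay under 4.54, for CLPs that of either group, the fold was taken with 4.54 in its place and is given as at least that value, while log2 differences are as measured.

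CD127+ LMPPs carried more transcript of lymphoid genes than CD127− LMPPs, and less of several monocyte and granulocyte progenitor genes. Il7r stood at 9.10 ± 0.05 (SD, n = 3) in CD127+ LMPPs and at 4.33 ± 0.44 (n = 3) in CD127− LMPPs, a difference of at least 23.6-fold that follows the sort (adjusted p = 1.03e-06). Ly6d, a marker of CLPs that lean to the B lineage, was higher by 3.91 log2, and the recombinase gene Rag1 by 3.22 log2 (both adjusted p = 1.03e-06). Of 11 mature granulocyte genes, 6 were higher as well. Among them Camp, which encodes cathelicidin, was 12.4-fold higher (adjusted p = 0.00065) and S100a8, a calprotectin subunit, 9.71-fold higher (adjusted p = 0.019). F13a1, the A subunit of coagulation factor XIII, was 8.54-fold lower (log2 difference −3.09, SE 0.26, adjusted p = 0.000168).

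The other largest measured increases in CD127+ LMPPs were in the guanylate-binding protein gene Gbp8 (log2 difference 3.59, adjusted p = 0.00247), the carbonic anhydrase gene Car1 (7.60-fold, adjusted p = 0.000274) and the chitinase-like gene Chi3l3 (at least 5.82-fold, adjusted p = 0.00571). The other largest measured decreases were in Clec9a, a dendritic cell receptor (at least 3.49-fold, adjusted p = 0.000368), Tfec (at least 4.18-fold), Nrp1 (at least 3.77-fold), the hepatocyte growth factor receptor gene Met (adjusted p = 0.00046), Ms4a6c (3.93-fold), the macrophage colony-stimulating factor receptor gene Csf1r (3.71-fold) and Tnfsf9 (at least 3.14-fold). Their adjusted p ran from 3.22e-05 to 0.00825. Kit (log2 difference −0.37, adjusted p = 0.262), Flt3 (0.34, adjusted p = 0.288) and Ly6a (1.21, adjusted p = 0.148) did not pass. The sort marker list, with 2 of 5 members higher and 4 higher and 1 lower adjusted over the list alone, was higher (camera adjusted p = 1.57e-07). For Il7r this restates the sort. The other called member was Ly6d, by which the LMPPs were not divided. Il7r is also on the early lymphoid list.

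Of 23 measured B lineage genes, 8 rose in CD127+ LMPPs and 15 did not pass, with 10 higher adjusted over the list alone (camera adjusted p = 3.53e-13). Ebf1, a transcription factor of B cell specification, rose by 2.57 log2 (SE 0.16, adjusted p = 2.66e-05), the adaptor gene Blnk by 2.40 (SE 0.14, adjusted p = 9.37e-06) and Rag2 by 1.96 (SE 0.22, adjusted p = 0.00116). Of 19 early lymphoid genes, 5 rose and 14 did not pass, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.28e-13): Il7r, Rag1, Rag2, Lax1 and Dntt. Of 22 T lineage and Notch genes, 3 rose and 19 did not pass, with 7 higher adjusted over the list alone (camera adjusted p = 1.89e-05): the Notch target Hes1 (log2 difference 1.63), Lat (1.43) and Cd247 (1.09), both parts of T cell receptor signalling. Of 25 innate lymphoid and NK genes, 5 rose and 1 fell, with 8 and 2 adjusted over the list alone (camera adjusted p = 4.62e-05). The 5 were Il18r1 (log2 difference 1.52), Ets1 (1.26), Tox (1.15), Il2rg and Il2rb, the last under the low-signal limit in both groups. The receptor gene Klrk1 fell by 1.68.

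Of 18 interferon response genes, 3 rose and 15 did not pass, with 11 higher adjusted over the list alone (camera adjusted p = 4.66e-11): Ifi44, Rtp4 and Irf7. Of 17 megakaryocyte and erythroid genes, 3 rose and 14 did not pass, with 11 higher adjusted over the list alone (camera adjusted p = 5.83e-10): Car1, Ermap (log2 difference 1.18, adjusted p = 0.00477) and Rhag. Of 11 mature granulocyte genes, 6 rose and 5 did not pass, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.13e-09, and adjusted p = 0.0947 with an estimated correlation). Besides Camp and S100a8, Ngp (log2 difference 2.54, adjusted p = 0.00134) and S100a9 (2.52, adjusted p = 0.00802) were among them. Of 22 myeloid genes, 8 fell and 1 rose, with 12 and 3 adjusted over the list alone (camera adjusted p = 9.18e-09, and adjusted p = 0.0682 with an estimated correlation). Csf1r, the neutrophil protease gene Ctsg (log2 difference −1.83, adjusted p = 0.000165), the chemokine gene Ccl9 (−1.65) and the myeloperoxidase gene Mpo (−1.31, adjusted p = 0.00144) fell, and the member that rose was Cd33.

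Smaller list differences between the LMPP groups lost their call with an estimated correlation. The dendritic cell and MHC class II list was higher with Siglech, Irf7 and H2-Eb1 higher and Clec9a lower among 19 genes, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0245, and adjusted p = 0.143 with an estimated correlation). The mature B and plasma cell list was higher with Ighm as the called gene of 11, also 1 adjusted over the list alone (camera adjusted p = 0.0217, and adjusted p = 0.0942 with an estimated correlation). The stroma and endothelium list was higher (camera adjusted p = 0.0245, and adjusted p = 0.313 with an estimated correlation), although limma called 0 of its 13 members, also when adjusted over the list alone, and 1 at an unadjusted p under 0.05. Kdr, under the low-signal limit in both groups, had its largest difference (0.37, adjusted p = 0.535). The cell cycle list was lower (camera adjusted p = 0.000869, and adjusted p = 0.143 with an estimated correlation): limma called 0 of 32 members, 1 lower adjusted over the list alone, and 3 lower and 1 higher at an unadjusted p under 0.05. The histone list was lower (camera adjusted p = 0.00121, and adjusted p = 0.173 with an estimated correlation): limma called 0 of 30 members, 0 adjusted over the list alone, and 7 lower at an unadjusted p under 0.05. Rrm2 (−0.62, adjusted p = 0.0561) and Hist1h4b (−0.72, adjusted p = 0.261), the second under the low-signal limit in both groups, were their largest differences. With quantile normalization the cell cycle and the stroma lists missed the threshold (adjusted p = 0.0603 and 0.0506).

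The other 8 lists did not pass camera between the LMPP groups, and fry called T cell receptor segments among them (adjusted p = 0.04). Their camera adjusted p was 0.0636 for stem and multipotent progenitor genes, with Mycn as the largest difference (0.70), 0.238 for homing and adhesion genes, of which Ccr2 fell by 1.69, and 0.179 for macrophage and monocyte genes, of which Ccr2 and Cd68 fell. It was 0.322 for immediate early and heat shock genes, of which Nr4a1 rose and Klf6 fell, 0.301 for ribosomal protein genes (largest difference Rpl3l, 0.77), and 0.486 for mitochondrial genome genes (ND2, −0.08). It was 0.17 for immunoglobulin segments (Ighv1-72, 1.06) and 0.0965 for T cell receptor segments (Trbv13-2, 0.48), both genes under the low-signal limit in both groups.

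**Figure D1:**
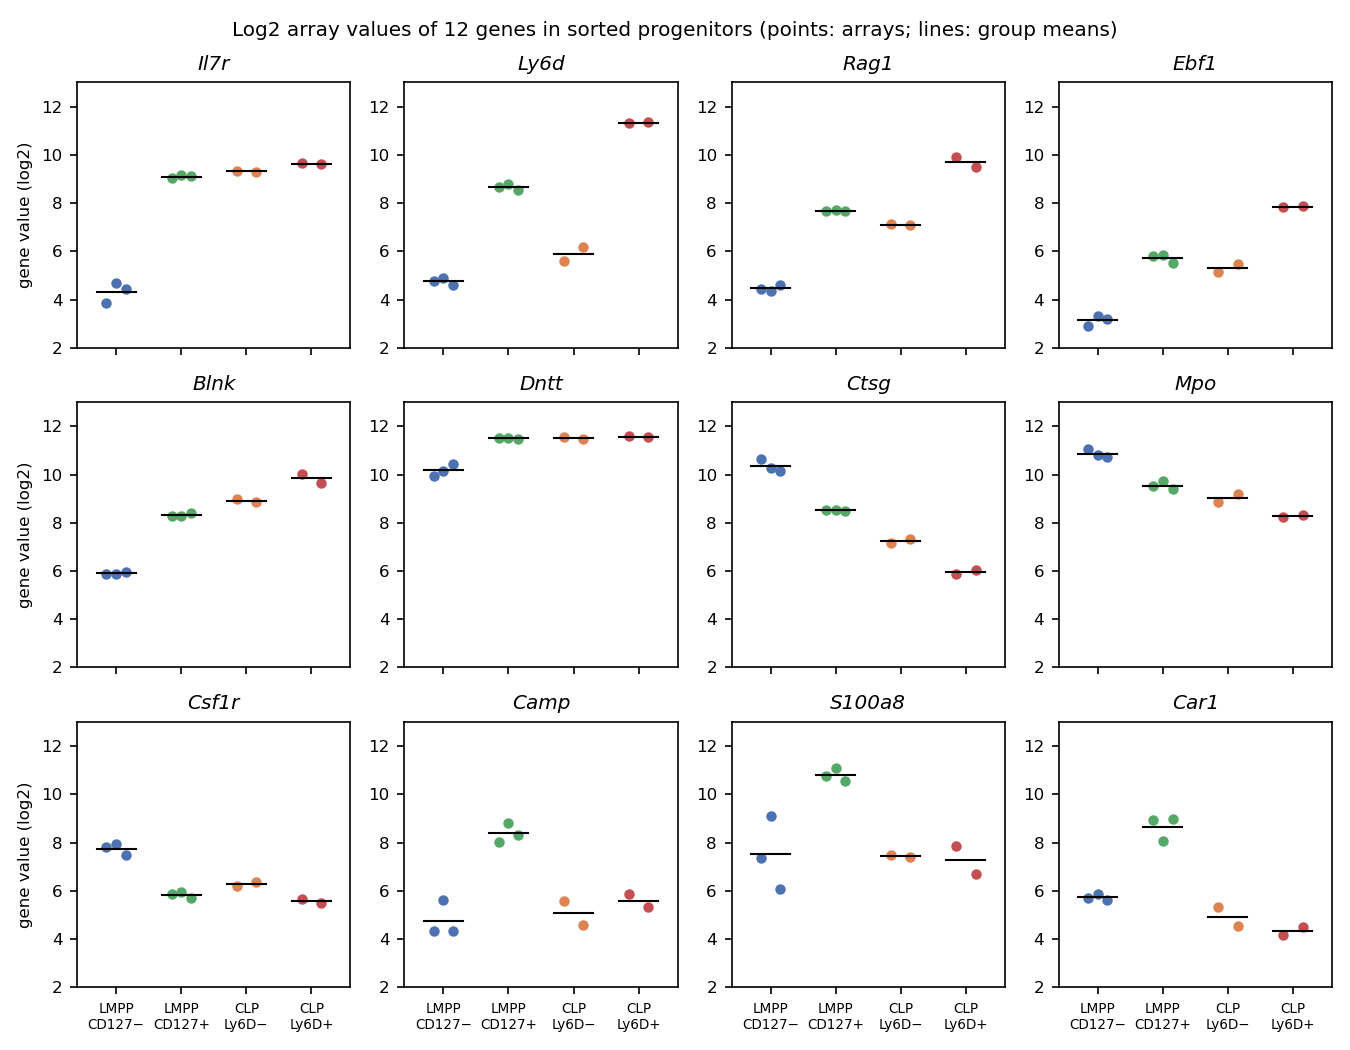
Log2 values of 12 genes (y axis) in each array of the 4 groups (x axis), with points for arrays and lines for group means. Il7r stood at a mean of 4.33 in CD127− LMPPs and 9.10 in CD127+ LMPPs, and Camp at 4.76 and 8.39.

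In all, limma called 204 genes higher and 137 lower in CD127+ than in CD127− LMPPs (341 of 23152), 169 of them by 2-fold or more, and 2571 had an unadjusted p under 0.05. With an array left out the count ran from 165 to 275, and 33 of the 44 named calls held without each array in turn and 14 in every setting tried. With the brightest probe set of each gene Ctsg, Mpo, Rag2, Nrp1, Met, Lat, Ngp and S100a9 were among the calls lost. Of the 11 calls lost without an array, S100a8, Lax1, Siglech, Irf7, H2-Eb1, Ifi44, Rtp4, Nr4a1, Klf6 and Ighm lost their call without CD127+ LMPP array 2 (adjusted p from 0.0516 to 0.183) and Rhag without CD127− LMPP array 3 (adjusted p = 0.0632). Each of the 6 LMPP arrays, when left out, ended between 6 and 10 of these calls.

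CLPs had less transcript of 7 of 11 mature granulocyte and 8 of 17 megakaryocyte and erythroid genes than CD127+ LMPPs. Both lists were lower by camera, with adjusted p = 0.192 and 0.0717 with an estimated correlation. Car1 was at least 15.2-fold lower in CLPs (log2 difference −4.03, SE 0.24, adjusted p = 5.97e-05), S100a8 10.9-fold lower (adjusted p = 0.0057) and Camp 8.28-fold lower (adjusted p = 0.00124). Mean Camp values were 8.39 ± 0.39 (SD, n = 3) in CD127+ LMPPs, 5.09 ± 0.71 (n = 2) in Ly6D− CLPs and 5.58 ± 0.37 (n = 2) in Ly6D+ CLPs. In CD127− LMPPs the Camp mean was 4.76 (n = 3), so CD127+ LMPPs were the highest group. Against CD127− LMPPs, the mature granulocyte list had a median log2 difference of 0.051 in CLPs, with 1 gene higher and 2 lower. The megakaryocyte and erythroid list had a median of −0.195, with 1 gene higher and 4 lower. Carry-over of mature cells into the CD127+ sort was not excluded for either list. Siglech, a receptor of plasmacytoid dendritic cells, was 3.54-fold higher in CLPs (log2 difference 1.82, SE 0.15, adjusted p = 0.000285). Il7r differed by 0.38 log2 (SE 0.18) and did not pass (adjusted p = 0.261).

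The other largest measured decreases in CLPs were in the metallothionein gene Mt2 (7.24-fold), the neutrophil elastase gene Elane (7.08-fold), Retnlg (at least 4.07-fold), Fdx1l (at least 1.21-fold) and Chi3l3 (at least 4.94-fold), with adjusted p from 0.00083 to 0.00403. The other largest measured increases were in Rbpms2 (at least 1.03-fold, adjusted p = 0.0169), the inflammasome gene Nlrp3 (3.27-fold), the granzyme gene Gzmc (at least 1.41-fold), the cytokine gene Il10 (2.94-fold), Skil (2.92-fold), the ephrin receptor gene Epha2 (2.78-fold) and Ddit3 (2.58-fold), a transcription factor of the stress response. Kit fell by 0.99 log2 (adjusted p = 0.00146), in the direction of the sort, and was the sort marker that passed, with 2 lower adjusted over the list alone. Flt3 (−0.004, adjusted p = 0.991) and Ly6a (−1.12, adjusted p = 0.0613) did not pass.

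Against CD127+ LMPPs, Ly6d had a log2 difference of −2.79 in Ly6D− CLPs (adjusted p = 0.00031) and 2.66 in Ly6D+ CLPs (adjusted p = 9.95e-05). For both CLP groups together it did not pass (−0.06, adjusted p = 0.872). Rag1 was 0.72 higher in CLPs (SE 0.13, adjusted p = 0.011), with 2.02 (adjusted p = 0.000164) in Ly6D+ and −0.58 (adjusted p = 0.0851) in Ly6D− CLPs. Of 23 B lineage genes, 7 rose in CLPs and 16 did not pass, with 9 higher adjusted over the list alone (camera adjusted p = 4.63e-06, and adjusted p = 0.0595 with an estimated correlation), among them Spib (log2 difference 1.22, adjusted p = 0.000957) and Blnk (1.07, adjusted p = 0.00149). By CLP group, Blnk differed by 1.53 in Ly6D+ CLPs (adjusted p = 0.000622) and by 0.61 in Ly6D− CLPs, which did not pass (adjusted p = 0.0654), and Spib by 1.61 (adjusted p = 0.00061) and 0.82 (adjusted p = 0.028). In Ly6D+ CLPs alone 12 B lineage genes rose, 16 adjusted over the list alone (camera adjusted p = 3.39e-13, and adjusted p = 0.0116 with an estimated correlation), and in Ly6D− CLPs alone 1 rose and 1 fell, 3 and 2 adjusted over the list alone (camera adjusted p = 0.469). Of 25 innate lymphoid and NK genes, 4 rose and 21 did not pass, with 5 higher adjusted over the list alone (camera adjusted p = 0.000408, and adjusted p = 0.0938 with an estimated correlation): Il18r1 (1.15), Il17rb, Il2rg and Klrk1, whose means lay under the low-signal limit in both CLPs and CD127+ LMPPs.

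Of 85 ribosomal protein genes, 10 fell and 2 rose in CLPs, with 13 and 4 adjusted over the list alone (camera adjusted p = 1.35e-05, and adjusted p = 0.0161 with an estimated correlation). Rpl30 (log2 difference −1.24, adjusted p = 0.00323), Rps27 (−1.23) and Rpl31 (−0.90) were among those that fell, and the risers were Rps15a-ps6, a pseudogene by its name, and Rpl3l, a paralog of Rpl3. Rps27 rests on 1 probe set and Rpl30 and Rpl31 on 2 each, against a median of 8 per gene. Of 17 megakaryocyte and erythroid genes, 8 fell and 1, Tfrc, rose, with 12 and 1 adjusted over the list alone (camera adjusted p = 5.4e-09, and adjusted p = 0.0717 with an estimated correlation). Car2 (−1.78) and Rhag (−1.30) were among those that fell. Of 11 mature granulocyte genes, 7 fell and 4 did not pass, the same count adjusted over the list alone (camera adjusted p = 4.84e-08, and adjusted p = 0.192 with an estimated correlation), S100a9 (−2.08) among them. Of 22 myeloid genes, 9 fell and 1, Ly86, rose, with 10 and 2 adjusted over the list alone (camera adjusted p = 4.45e-06, and adjusted p = 0.192 with an estimated correlation). The protease genes Prtn3 (−2.33) and Ctsg (−1.91) were among those that fell.

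Of 20 stem and multipotent progenitor genes, 5 fell and 1, Mllt3, rose in CLPs, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.000408, and adjusted p = 0.2 with an estimated correlation). The 5 were Gata2 (adjusted p = 0.00586), Hlf, Cd34 (log2 difference −0.70), Hoxa9 and Ndn. Of 30 histone genes, 5 fell and 25 did not pass, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.322 with an estimated correlation), Hist1h4h (−1.28) and Hist1h4m (−1.04) among them. The interferon list was lower, with Rsad2 higher and Ifi27l2a lower among 18 genes and 1 and 4 adjusted over the list alone (camera adjusted p = 0.0374, and adjusted p = 0.322 with an estimated correlation). It missed the threshold with quantile normalization (adjusted p = 0.0924). The other 13 lists did not pass camera, with adjusted p from 0.0667 for macrophage and monocyte genes to 0.995 for cell cycle genes and immunoglobulin segments. Of these, fry called sort markers (adjusted p = 0.0108) and the dendritic cell (0.0111), macrophage (0.0261) and T lineage (0.0353) lists. Camera after quantile normalization called mitochondrial genome (0.0376) and macrophage genes (0.0407). Among 19 dendritic cell and MHC class II genes, 6 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.113), with Irf4 among the risers (0.95). Of 19 early lymphoid genes Rag1 passed, and of 22 T lineage and Notch genes Lef1 passed.

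In all, 517 genes were higher and 913 lower in CLPs than in CD127+ LMPPs, 1430 of 23152, and 217 differed by 2-fold or more. With quantile normalization the division was 685 higher and 748 lower, so higher calls made up 36.2% as deposited and 47.8% after it. With an array left out the count ran from 586 to 1163, and with a replicate block it was 755. Of the 57 named calls 36 held without each array in turn and 22 in every setting tried, and each of the 7 arrays, when left out, ended between 5 and 20 of them. Of the genes named here, Rbpms2, Il17rb, Il2rg, Lef1, Hoxa9, Rsad2 and Ifi27l2a lost theirs without Ly6D+ CLP array 1 (adjusted p from 0.052 to 0.0763) and Hlf without CD127+ LMPP array 1 (adjusted p = 0.0542). An array batch cannot be told apart from the difference between LMPPs and CLPs.

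CLPs and CD127− LMPPs differed in more genes than the other pairs compared, with lymphoid genes higher and myeloid genes lower in CLPs. Il7r was at least 30.6-fold higher in CLPs (log2 difference 5.15, SE 0.18, adjusted p = 1.34e-07), as the sort requires. Rag1 was at least 14.6-fold and Ebf1 at least 4.09-fold higher, and Blnk was higher by 3.46 log2, with adjusted p from 1.34e-07 to 4.59e-07. Ctsg was 13.4-fold lower (log2 difference −3.74, SE 0.14, adjusted p = 1.48e-07): its means were 10.35 ± 0.26 (SD, n = 3) in CD127− LMPPs, 8.51 ± 0.04 (n = 3) in CD127+ LMPPs, 7.25 ± 0.12 (n = 2) in Ly6D− CLPs and 5.96 ± 0.10 (n = 2) in Ly6D+ CLPs.

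Besides these, Gbp8 (at least 12.1-fold), Ly6d (14.4-fold), the sialyltransferase gene St6gal1 (at least 5.56-fold) and Gbp9 (at least 5.55-fold) had the largest measured increases over CD127− LMPPs, with adjusted p from 2.52e-07 to 6.02e-05. The Ly6d value averages CLP groups that were divided by Ly6D. Its arrays stood at 5.594 and 6.17 in Ly6D− CLPs, 11.305 and 11.355 in Ly6D+ CLPs, and 4.608 to 4.908 in CD127− LMPPs. F13a1 (at least 11.2-fold), Prtn3 (at least 9.81-fold), Anxa3 (at least 7.98-fold), the melanocortin receptor gene Mc5r (at least 7.11-fold), Ccl9 (8.85-fold), Lst1 (8.83-fold) and Tfec (at least 4.18-fold) had the largest measured decreases among the genes that the naming rule admits, with adjusted p from 1.89e-06 to 0.000115. Scarna2, a small RNA gene that the rule leaves out, fell further and is given under the other observations. Kit fell by 1.36 log2 (adjusted p = 5.63e-05), while Flt3 (0.34, adjusted p = 0.0747) and Ly6a (0.09, adjusted p = 0.896) did not pass. The sort marker list, with 2 members higher and 1 lower, and 3 and 1 adjusted over the list alone, was higher (camera adjusted p = 0.0134, and adjusted p = 0.156 with an estimated correlation), and again holds Il7r, on which these groups were sorted.

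Of 23 B lineage genes, 17 rose in CLPs over CD127− LMPPs and 6 did not pass, with 18 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.54e-14), among them Blk (log2 difference 2.59, adjusted p = 0.000249). Of 22 myeloid genes, 12 fell and 1, Cd33, rose, with 15 and 1 adjusted over the list alone (camera adjusted p = 1.07e-12), Elane (−2.37, adjusted p = 0.00344) among those that fell. Of 25 innate lymphoid and NK genes, 11 rose and 1, Itgb7, fell, with 12 and 1 adjusted over the list alone (camera adjusted p = 2.02e-06). Il18r1 (2.67), Tox (1.53), Il2rg (1.38) and Il2rb (1.16) led the risers by measured difference. Il2rb lay under the low-signal limit in CD127− LMPPs, and its fold was at least 1.03. Of 22 T lineage and Notch genes, 9 rose and 13 did not pass, with 11 higher adjusted over the list alone (camera adjusted p = 2.14e-05). Hes1 (1.67), Cd5 (1.31), Cd247 (1.18) and Lat (1.12) had the largest differences. Of 19 early lymphoid genes, 11 rose and 8 did not pass, with 13 higher and 2 lower adjusted over the list alone (camera adjusted p = 9.96e-09, and adjusted p = 0.089 with an estimated correlation), Rag2 (1.56) and Dntt (1.37) among them.

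Of 85 ribosomal protein genes, 21 fell and 4 rose in CLPs relative to CD127− LMPPs, with 30 and 6 adjusted over the list alone (camera adjusted p = 8.75e-06, and adjusted p = 0.00726 with an estimated correlation). Rpl34 (log2 difference −1.63, adjusted p = 0.0012), Rps27 (−1.21) and Rpl30 (−1.15) had the largest decreases, and the risers were Rpl3l, Rps6ka6, Rps15a and Rpl32. Rpl34 and Rps27 rest on 1 probe set each and Rpl30 on 2, against a median of 8 per gene. Of 30 histone genes, 7 fell and 23 did not pass, with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.46e-05, and adjusted p = 0.134 with an estimated correlation), Hist1h4m (−1.27) and Hist1h1b (−1.17) among them. Of 18 interferon genes, 2 rose, Ifi44 (1.08) and Rsad2, with 3 adjusted over the list alone (camera adjusted p = 0.00309, and adjusted p = 0.156 with an estimated correlation). Of 19 dendritic cell and MHC class II genes, 6 rose and 3 fell, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.134 with an estimated correlation). Siglech (2.73) and Irf4 (1.54) were higher and Ly6c2 (−1.94) and Clec9a (−1.39) lower. Of 11 mature B and plasma cell genes, Ighm rose (0.62, camera adjusted p = 0.0134, and adjusted p = 0.089 with an estimated correlation), with 2 adjusted over the list alone. Of 32 cell cycle genes, 4 fell, Rrm2 (−0.72), Cdc20 (−0.71), Gins2 (−0.56) and Plk1, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.271 with an estimated correlation, and 0.256 with quantile normalization).

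The other 10 lists did not pass camera between CLPs and CD127− LMPPs, with adjusted p from 0.072 for macrophage and monocyte genes, of which 5 fell, to 0.987 for mature granulocyte and homing genes. Of these, fry called macrophage genes (adjusted p = 0.00198), T cell receptor segments (0.00472), stem and multipotent progenitor (0.0354) and immediate early genes (0.038), and camera after quantile normalization called immediate early (0.0207) and macrophage genes (0.0229). The 5 macrophage and monocyte genes were Ccr2 (log2 difference −2.10), Ly6c2, Cd68 (−1.31), Cd14 (−1.12) and Emr1. Mature granulocyte genes, of which 6 of 11 were higher in CD127+ than in CD127− LMPPs, had 1 riser, Ngp. Another 2 fell, Mmp8 and Cxcr2, neither of them among the 6. The counts were the same adjusted over the list alone. Of 16 immediate early and heat shock genes, 4 rose and 1 fell, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.111), Nr4a1 (1.43), Btg2 (0.94) and Fosb (0.92) among the risers. Gata2 (−1.44), Hlf (−1.17), Cd34 (−0.87) and Angpt1 fell and Mllt3 (0.85) and Eya1 rose among 20 stem and multipotent progenitor genes (camera adjusted p = 0.124). Tfrc (0.98) rose and 4 megakaryocyte and erythroid genes, Car2 (−1.13), Car1, Nfe2 (−0.82) and Tal1, fell (camera adjusted p = 0.155).

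**Figure D2:**
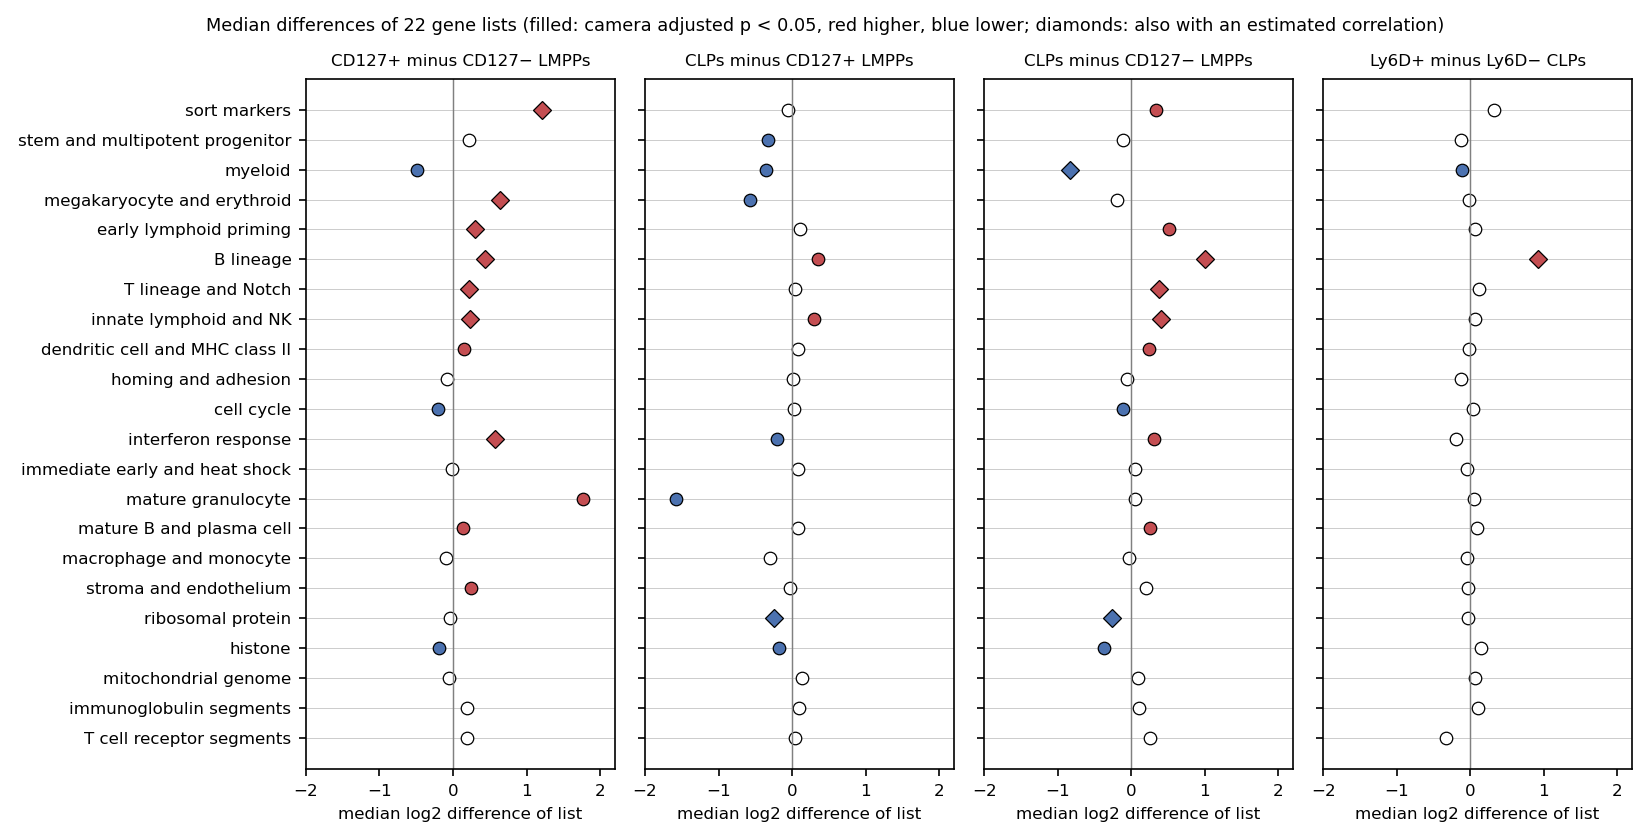
Median log2 difference (x axis) of each of 22 gene lists (y axis) in 4 comparisons; filled points passed camera, and diamonds also passed with an estimated correlation. The B lineage list had a median of 1.00 between CLPs and CD127− LMPPs and 0.92 between the CLP groups, and the mature granulocyte list 1.77 between the LMPP groups.

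In all, 1175 genes were higher and 1936 lower in CLPs than in CD127− LMPPs, 3111 of 23152, and 582 of them differed by 2-fold or more. With quantile normalization the division was 1366 higher and 1420 lower, so higher calls made up 37.8% as deposited and 49% after it. With an array left out the count ran from 1763 to 2904, and 61 of the 71 named calls held without each array in turn and 43 in every setting tried. Ngp, Cxcr2, Rsad2, Mmp8, Plk1 and Egr1 lost theirs without Ly6D+ CLP array 2 (adjusted p from 0.0515 to 0.0891). Ccr9 and Itga4 lost theirs without CD127− LMPP array 1 (0.101 and 0.0525), Car1 without CD127− LMPP array 2 (0.0505) and Trav9d-3 without CD127− LMPP array 3 (0.059). Each of the 7 arrays ended between 1 and 7 of these calls.

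Few genes were called between Ly6D+ and Ly6D− CLPs, led by genes of the B lineage. With 2 arrays in each group many differences can be missed: 38.8% of the simulated log2 changes of 1 were recovered in this comparison. Ly6d stood at 11.33 ± 0.04 (SD, n = 2) in the Ly6D+ and 5.88 ± 0.41 (n = 2) in the Ly6D− group, a 43.7-fold difference that follows the sort (adjusted p = 6.43e-07). Rag1 was 6.06-fold (adjusted p = 0.00013), Ebf1 5.85-fold (adjusted p = 0.000292) and the surrogate light chain gene Vpreb2 5.51-fold higher (adjusted p = 0.000225). Gfra2, a receptor of glial cell line-derived neurotrophic factor ligands, was at least 3.17-fold higher (adjusted p = 0.000292). Cpa3, the mast cell carboxypeptidase gene, was at least 3.07-fold lower in Ly6D+ CLPs (log2 difference −2.12, SE 0.23, adjusted p = 0.00509), and Prss3, under the low-signal limit in both groups, was lower (adjusted p = 0.00195).

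Trem1 (at least 3.90-fold), Cecr2 (at least 2.64-fold) and Lynx1 (log2 difference 1.85) were also higher, and Mc5r (at least 1.81-fold), Lst1 (2.80-fold), Slc22a3 (2.74-fold), Gcnt2 (2.49-fold), Ctsg (2.44-fold) and Ap1s2 (at least 1.98-fold) lower, with adjusted p from 0.0105 to 0.0461. Of 23 B lineage genes, 3 rose and 20 did not pass, with 14 higher adjusted over the list alone (camera adjusted p = 5.1e-21, and adjusted p = 0.00343 with an estimated correlation): Rag1, Ebf1 and Vpreb2. Of 22 myeloid genes, 1, Ctsg, fell, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0114, and adjusted p = 0.529 with an estimated correlation). The other 20 lists did not pass camera, with adjusted p from 0.0595 for stem and multipotent progenitor genes to 0.998 for innate lymphoid, immediate early and stroma genes. Of these, fry called sort markers (adjusted p = 0.000389), and camera after quantile normalization called the stem and early lymphoid lists (both 0.0199) and T cell receptor segments (0.0371). Among the values that did not pass were Tcf7, a transcription factor of the T lineage (log2 difference −1.25, adjusted p = 0.0546), Siglech (1.21, adjusted p = 0.0574) and Il7r (0.33, adjusted p = 0.723).

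In all, 9 genes were higher and 14 lower in Ly6D+ CLPs, 23 of 23152, and 2107 had an unadjusted p under 0.05. Of the 16 largest, Ly6d, Rag1, Ebf1, Vpreb2, Gfra2 and Prss3 held with each array left out in turn, and the 10 others lost their call without Ly6D+ CLP array 2 (adjusted p from 0.0677 to 0.291). Between 6 and 8 of the 10 were also lost without each of the other 3 CLP arrays. With the CLP arrays fitted alone, Ly6d was the 1 gene called, and it was the 1 of the 16 that held in every setting tried.

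Across all genes, the LMPP difference by CD127 and the CLP difference by Ly6D, which share no arrays, correlated at Pearson r of 0.184, with a covariance of 0.0169; genes are not independent replicates. Of the 341 genes called between the LMPP groups, 246 (72.1%) had the same sign between the CLP groups, against 55.8% of all genes. Ebf1, Ly6d, Rag1 and Vpreb2 were higher in both comparisons, 4 genes where independent lists would share 0.0793. Between the CLP groups the Ly6d call follows the sort. Ctsg, F630028O10Rik, Lst1, Mc5r and Rab38 were lower in both, 5 genes where independent lists would share 0.0828. Both expected counts take all genes as equally likely to be called, which sets them too low. Of the dim sensory receptor genes, 0.14% were called between the LMPP groups and 0% between the CLP groups, against 1.56% and 0.11% of other genes. Of the 204 genes higher in CD127+ LMPPs, 160 were also higher in CLPs than in CD127− LMPPs, and of the 137 lower genes 117 were also lower. Both comparisons use the CD127− arrays: data with no effect, simulated 20 times, correlated at r of 0.534 against 0.604 measured, with a covariance of 0.0238 against 0.0724. With separate CD127− arrays in the 2 comparisons, over the 6 ways to part them, the covariance had a mean of 0.0495 (0.0440 to 0.0576) and r a mean of 0.336 (0.277 to 0.383). The count of shared calls was not recomputed this way. Of the same 204 genes, 31 were higher and 33 lower in CLPs than in CD127+ LMPPs, and of the 137, 12 were higher and 18 lower. Over all 23152 genes, 517 were higher and 913 lower. Here the CD127+ arrays are shared with opposite sign, which pushes the 204 genes toward lower and the 137 toward higher, and no value without effect was computed.

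**Figure D3:**
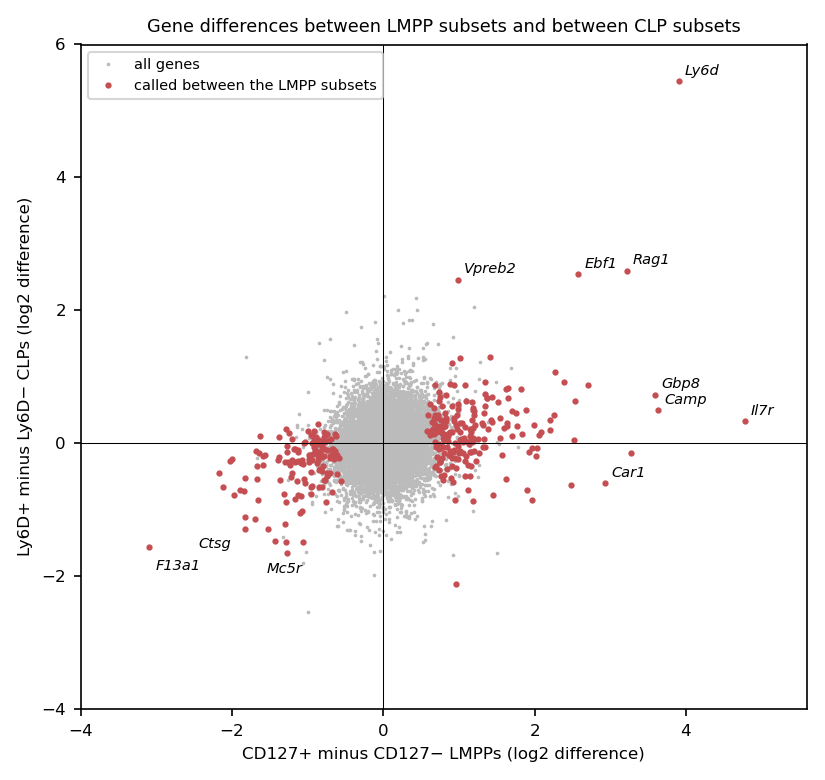
Log2 difference of each gene between the LMPP groups (x axis) and between the CLP groups (y axis), with the genes called between the LMPP groups in red. Ly6d (3.91 and 5.45), Rag1 (3.22 and 2.60) and Ebf1 (2.57 and 2.55) lay far up in both, and Il7r (4.78 and 0.33) in the first.

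The mean squared log2 difference over all genes, after subtraction of its sampling variance, was 0.0399 between the LMPP groups, 0.0685 between CLPs and CD127+ LMPPs, 0.127 between CLPs and CD127− LMPPs and 0.0291 between the CLP groups. With an array left out the values ran from 0.0326 to 0.0518, 0.0648 to 0.0768, 0.117 to 0.139 and 0.0197 to 0.0797 in that order. In the called lists the median, mean and test had the same sign in every comparison. Among lists not called, the signs differed for immediate early genes between the LMPP groups, for immunoglobulin segments and cell cycle genes between CLPs and CD127+ LMPPs, for mature granulocyte genes between CLPs and CD127− LMPPs, and for innate lymphoid, dendritic cell, stroma and immediate early genes between the CLP groups.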

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

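The tests of an array batch and of the normalization, and the alternatives without small RNA and sensory receptor genes or without the 2 arrays of largest residual spread, were chosen only after the results were seen.

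Between the LMPP groups, probe sets outside the gene tests also carried signal. Of 30892 probe sets with no gene symbol, 20 were higher and 1 lower in CD127+ LMPPs. Of 5106 probe sets with several symbols, 7 were higher and 0 lower by limma.

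In CD127+ LMPPs, 6 of 11 mature granulocyte genes (list adjusted p = 0.0947 with an estimated correlation) and 3 of 17 megakaryocyte and erythroid genes were higher, 7 and 11 adjusted over each list alone, where a lineage-negative sort would remove the mature cells. Neutrophils carried over in the sort may bring such transcripts. A second neutrophil list of 23 genes, without the 3 that the fixed lists hold, had a median log2 difference of 0.203 (bootstrap interval over genes −0.076 to 0.364). In it Fcnb was higher and Slpi (−1.21) lower. Its most abundant genes Serpinb1a at 9.71 against 9.73 (limma adjusted p = 0.974) and Alox5ap at 8.98 against 9.16 (adjusted p = 0.668) did not pass. Both were also bright in Ly6D− and Ly6D+ CLPs (Serpinb1a 9.27 and 9.23, Alox5ap 8.45 and 8.18). A small share of neutrophils would hardly move genes this bright, so these 2 values decide nothing. The prediction written beforehand put the limit for carry-over at a median above 0.5 and the limit against it at 0.2. The fixed mature granulocyte list had a median of 1.77. The median of 0.203 for the second neutrophil list lies between the limits, so the test leaves neutrophils open. A first run took the whole list by mistake and gave 0.213. Erythroid cells could account for the erythroid genes: the second erythroid list of 17 genes, without the 5 that the fixed lists hold, had a median of 0.393 (interval 0.253 to 0.624), again between the limits, with Rhd and Kel higher and Alas2 at 4.52 against 4.18 not past the threshold (whole list, by the same mistake, 0.493). An eosinophil and basophil list of 15 genes had a median of 0.192, and of 0.214 without the 1 that the fixed lists hold. In it Prg2 and Cpa3 were higher and Mcpt8 lower. Among CD127+ LMPP arrays, array 2 was highest for Camp, S100a8, S100a9, Ngp and, at 7.684 against 5.968 and 6.045, Retnlg. It was lowest for Car1 (8.063 against 8.932 and 8.971), Rhag, Ermap, Pf4 and Car2, but not for Tfrc and Nfe2. CD127− array 2 was highest for the same granulocyte genes, and for Car1. Varying shares of carried-over cells could give this, as could varying expression by the progenitors, and neither was tested. Expression of all these genes by CD127+ LMPPs themselves stays open as the untested biological explanation.

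The dimmest of 4 equal groups of genes had a median log2 difference of 0.098 and 0.083 in CLPs against CD127− and CD127+ LMPPs, and of 0.01 and 0.001 within LMPPs and within CLPs, a shift that an array or labelling batch could give. Sensory receptor genes were called for 2.46% of 1384 genes (34, Clopper-Pearson 95% interval 1.71 to 3.42) between CLPs and CD127− LMPPs, against 0.14% (2 genes) between the LMPP groups, which met the criterion of over 3 times set for a batch. That criterion decides nothing, because the p limit of a call was 0.00672 in the first comparison and 0.000723 in the second; at an unadjusted p under 0.05 the shares were 13.01% between CLPs and CD127− LMPPs, 11.49% between CLPs and CD127+ LMPPs, 6.86% between the LMPP groups and 12.14% between the CLP groups, where no boundary between LMPP and CLP arrays lies. Their median log2 difference did follow that boundary, at 0.116 and 0.109 for CLPs against CD127− and CD127+ LMPPs, 0.043 and 0.04 after quantile normalization, and 0.008 and 0.007 within LMPPs and within CLPs. As LMPPs and CLPs were each registered together, a batch and the difference between them cannot be told apart.

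More genes were lower than higher in CLPs than in CD127− LMPPs, and the ribosomal protein list was lower. The spread of the arrays may give the first pattern: the median log2 difference in 4 equal groups of genes from dimmest to brightest was 0.098, 0.065, −0.092 and −0.09, and with quantile normalization it was 0.012, 0.003, −0.013 and 0.009 while higher calls came to 49% of all calls, from 37.8%. Shifts also lay within LMPPs (0.01, 0.064, −0.005 and −0.074) and within CLPs (0.001, 0.091, −0.019 and −0.057), where higher calls made up 59.8% and 39.1%, and 61.7% and 46.7% with quantile normalization, so these values go both ways. With each array centred on its median, calls were 157 higher and 151 lower within LMPPs, and 1070 higher and 1992 lower in CLPs against CD127− LMPPs. The ribosomal protein list kept its lower call with quantile normalization (camera adjusted p = 0.00135), which argues against array spread as its whole cause; for both patterns a difference between the cell types, untested, or an array batch stays open.

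Other splits of the arrays were tested with a 2-group limma fit. Between the LMPP groups the real split gave 271 genes and the highest other split 0, but the 10 splits, of which 1 gave as many, are too few for a share under 0.05. The real split of CLPs and CD127+ LMPPs gave 841 genes and the highest other 1, and that of CLPs and CD127− LMPPs gave 2348 and 1. In each, 1 of 35 splits, the real one, gave as many, a share under 0.05. Every other split mixed LMPP with CLP arrays, which puts any difference between them into the error and leaves few calls. The test therefore excludes no cause of these counts. The real split also follows the blocks in which the arrays were registered.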

How the results depend on the processing

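The alternative without the 2 arrays of largest residual spread was chosen after seeing the data. The counts of genes past the threshold, in the order LMPP groups, CLPs against CD127+ LMPPs, CLPs against CD127− LMPPs and CLP groups, were 341, 1430, 3111 and 23 and moved by over 1.5 times as follows. The median of probe sets gave 160, 641, 1822 and 11, and the brightest probe set 88 between the LMPP and 11 between the CLP groups. Dropping the dimmer genes, fewer tested, gave 526, 2512 and 68 in the LMPP, CD127+ and CLP comparisons, and trend and robust settings 581, 2415 and 78. The compared arrays alone gave 872 against CD127+ LMPPs and 1 between the CLP groups, the replicate block 755 and 8, and array weights 13 between the CLP groups. Residuals of 13 pairs with the same replicate number correlated at −0.043 to 0.127, so no strong pairing by number was seen. In a CLP group of 2 arrays the residuals mirror each other, so most of these pairs tell little. Whether arrays with the same number were prepared together cannot be told from these values. The 2-fold limit, stricter by construction, gave 169, 217 and 582. Ly6D− CLPs alone gave 476 against CD127+ and 1643 against CD127− LMPPs, and Ly6D+ CLPs alone 933 against CD127+ LMPPs. Without the 2 arrays, the counts were 205, 2025 against CD127− LMPPs and 12 between the CLP groups. With an array left out, where fewer arrays widen the error and a lone CLP array is assumed to vary like the other groups, the range was 165 to 275 (CD127− 1 168, CD127− 2 220, CD127+ 1 177, CD127+ 2 200, CD127+ 3 165), 586 to 1163 (CD127+ 1 608, 2 586, 3 600, Ly6D+ 1 647, Ly6D+ 2 715), 1763 to 2904 (CD127− 1 1763, CD127− 2 2023) and 6 to 27 (Ly6D− 2 9, Ly6D+ 1 8, Ly6D+ 2 6). The lists past the threshold fell from 14, 9, 12 and 2 to 7, 1, 5 and 1 with an estimated correlation, became 5 between the CLP groups with quantile normalization, and with an array left out ran from 12 to 14, 7 to 11, 12 to 13 and 1 to 4 (without Ly6D+ 1 and Ly6D+ 2). The correlation of 0.184 became 0.274 without dimmer genes and ran from 0.112 to 0.203 with an array left out. The mean squared differences without dimmer genes were 0.0713, 0.117 and 0.219 in the first 3 comparisons, 0.0847 and 0.151 by the median of probe sets for CLPs against CD127+ and CD127− LMPPs, and between the CLP groups 0.0797 without Ly6D− 1 and 0.0197 without Ly6D+ 2. For CLPs against CD127+ LMPPs, Ly6d turned to 0.75 and Pf4 to 0.62 with the brightest probe set, Ly6d to 2.66 with Ly6D+ CLPs alone, and Rag1 to −0.58 and Cd79a to −0.048 with Ly6D− CLPs alone, and against CD127− LMPPs Mmp8 turned to 0.14 with the brightest probe set. Over all settings of the named genes, 3684 values kept direction and side of the threshold, 480 lost and 35 gained a call, 18 moved and 6 reversed. Apart from fewer genes or arrays, the cause was not tested. Genes under 4.54, the 95th percentile of sensory receptor genes, are limited by signal over background.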

Other observations

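The families below were chosen after their values were seen, and no test of an explanation was run on them.

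Guanylate-binding protein genes, GTPases induced by interferon, rose in part in CD127+ LMPPs. Of 11 measured Gbp genes, 5 rose over CD127− LMPPs, with a median log2 difference of 1.69, and 8 rose in CLPs over CD127− LMPPs, with a median of 2.02. Besides Gbp8, Gbp4 rose by 2.02 (SE 0.17, adjusted p = 0.000168) and Gbp9 by 1.89 (SE 0.23, adjusted p = 0.00192) in CD127+ LMPPs, and Gbp6 (1.82, adjusted p = 0.0195) and Gbp7 (1.05, adjusted p = 0.0147) rose as well, while the 6 others did not pass: Gbp11 (1.78, adjusted p = 0.132), Gbp10 (1.69, adjusted p = 0.0572), Gbp2 (0.26), Gbp5 (0.04), Gbp1 (0.01) and Gbp3 (−0.19). In CLPs over CD127+ LMPPs 4 rose, and between the CLP groups limma called 0, with 2107 genes of all kinds at an unadjusted p under 0.05.

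Gimap genes, GTPases of lymphocyte survival, followed the same direction. Of 8 measured genes, 6 rose in CD127+ LMPPs, with a median log2 difference of 1.16, and 7 rose in CLPs over CD127− LMPPs, with a median of 1.46. Gimap7 rose by 1.83 (SE 0.30, adjusted p = 0.0108), Gimap4 by 1.41 (SE 0.17, adjusted p = 0.00185) and Gimap6 by 1.22 (SE 0.17, adjusted p = 0.00408) in CD127+ LMPPs. With quantile normalization the medians of the Gbp and Gimap genes between the LMPP groups were 1.62 and 1.18.

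Of 83 small nucleolar and Cajal body RNA genes, 12 were lower and 3 higher in CLPs than in CD127+ LMPPs, and 12 lower and 4 higher than in CD127− LMPPs. These were 18.07% and 19.28% of the genes, against 6.13% and 13.42% of all other genes. The 83 genes were brighter, with a median level of 6.88 in CD127+ LMPPs against a median of 4.59 for all genes. Dim genes are called less often: for sensory receptor genes the shares were 1.08% and 2.46%. Brightness was not matched, so it may account for some or all of the excess. The median log2 difference of the 83 genes against CD127− LMPPs was −0.138, and −0.05 with quantile normalization. An array batch cannot be told apart from differences between LMPPs and CLPs, these included. Scarna2 (log2 difference −5.71, SE 0.42, adjusted p = 2.19e-05) and Scarna13 (−2.99, SE 0.20, adjusted p = 1.36e-05) were lower in CLPs than in CD127− LMPPs, and neither passed between the LMPP groups.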
